A study of Mus musculus with 4 samples.

How the data were processed

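RNA sequencing of 4 libraries was used: 2 from E14Tg2A cells infected with a lentivirus carrying a control hairpin and 2 from cells infected with a hairpin against Rif1, each collected on day 4. The cells were grown in serum and leukemia inhibitory factor, and libraries were made with a TruSeq RNA kit, per the labels. The series also describes chromatin and DNA methylation assays, which were not used here, and repeat families were not analysed here.

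FPKM values (fragments per kilobase of transcript, scaled to the mapped total) were computed by the authors before deposition, 1 per RefSeq transcript, with TopHat2 2.0.4, Cufflinks 2.0.2 and the mouse genome mm9 named in their processing notes. Whether the values count reads or fragments is not given in the sources used here. The depth was read from the steps between low FPKM values of genes with 1 transcript over 2500 bases, where 60.0% to 62.0% of values lay within 0.1 of a whole step, against 20% by chance. The FPKM sums were 531351.5 and 490410.7 in the controls and 435556.8 and 424456.7 in the knockdown libraries.

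Of 32835 transcripts, 28540 were mRNA and 4295 non-coding RNA. Gene symbols came from RefSeq (32422 transcripts) and GENCODE (182) for GRCm38, a later build than mm9 that was used only for names, lengths and sequences, and 231 unmatched transcripts were kept under their own identifier. FPKM of transcripts with the same symbol were summed, giving 24016 genes, 4822 with several transcripts. The 11786 genes at 1 FPKM or more in at least 2 of the 4 libraries were kept. No other rescaling was applied.

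Knockdown and control were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term, an intensity trend, two-sided tests and Benjamini-Hochberg adjustment over the genes kept, at a threshold of 0.05. The prior had 5.52 degrees of freedom and the test 7.52. A total of 23 gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists, and list members were also tested with adjustment over the list alone. With an estimated correlation camera draws only on the residual degrees of freedom of the 4 libraries, so it had little power here. A list of genes encoded by mitochondrial DNA had 0 measured members. Genes named in the text are Rif1, the 12 characterised genes with the highest and the 12 with the lowest log2 fold change among those past the threshold with groups that do not overlap, up to 4 members of each list with the smallest p, and a fixed set of pluripotency, 2-cell, silencing and reference genes, of which Gata6 was not kept. These rules, the lists, the test and the alternatives were set before the data were examined, except where stated.

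Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, a common sum per library, no trend, the replicate number as a block, each library left out, the highest transcript per symbol in place of the sum, and a 2-fold minimum. Leaving out small RNA genes, and the block together with median-of-ratios scaling, were added after seeing the data. Shared sequence of the 2-cell list was measured as the share of 31-base words found in transcripts of another gene. Tested on simulated data of the same size, limma recovered 0% of genes changed 1.5-fold or 2-fold, 75.5% at 4-fold and 92% at 8-fold, with 0, 0, 7 and 7 false calls. The simulation modelled neither sequencing depth nor the shift of the median gene. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.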

Results

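RNA was sequenced from E14Tg2A cells, an established mouse embryonic stem cell line grown here in serum and leukemia inhibitory factor, 4 days after infection with a lentivirus carrying a short hairpin RNA. The 2 control libraries came from cells given a control hairpin and the 2 knockdown libraries from cells given a hairpin against Rif1, a chromatin-bound protein that regulates the timing of DNA replication. The study's title names the repression of endogenous retroviruses by Rif1 as its subject, and the comparison asks which genes differ between the knockdown and the control cells 4 days after infection. Each library listed 32835 RefSeq transcripts in FPKM (fragments per kilobase of transcript, scaled to the mapped total), at a depth of about 28900000 and 29300000 reads or fragments in the controls and 29900000 and 27700000 in the knockdown libraries as read from the steps of the low values. At that depth 1 FPKM in a transcript of 2 kb stands for 55.4 to 59.8 reads or fragments. The number of genes at 1 FPKM or more was 12082 and 11357 in the controls and 11578 and 10980 in the knockdown libraries. Nothing in the labels states that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

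Rif1 was present at 64.1 and 97.3 FPKM in the controls and at 6.73 and 10.8 FPKM in the knockdown libraries. The means were 80.7 ± 23.5 FPKM and 8.78 ± 2.89 FPKM (SD, n = 2 libraries each), a 9.20-fold lower level in the knockdown. Genes of the 2-cell embryo, a set that embryonic stem cells transcribe in rare cells and that often use the long terminal repeat of the retrovirus MERVL as a promoter, rose in the knockdown: 37 of 62 measured members rose and 0 fell, with a median log2 fold change of 2.89 (camera adjusted p = 5.63e-60 with a preset correlation, adjusted p = 0.772 with an estimated correlation). Among them Zscan4c, which acts in telomere maintenance of these cells, went from 68.3 and 334 FPKM to 1096 and 2160 FPKM. Genes of glycolysis and the response to low oxygen lay lower in the knockdown: 6 of 27 fell and 0 rose, with a median log2 fold change of -1.27 (camera adjusted p = 2.07e-07 with a preset correlation, adjusted p = 0.772 with an estimated correlation).

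Rif1 had a log2 fold change of -3.07 (SE 0.29, adjusted p = 0.00713, limma with Benjamini-Hochberg adjustment). Its direction held in each alternative tried, and its adjusted p left the threshold when the libraries were rescaled by median-of-ratios factors (0.0778) or quantile normalization (0.095), when genes were not filtered (0.203), without knockdown library 1 (0.139) and without knockdown library 2 (0.0953). With 2 libraries against 2, an exact two-sided permutation test of 1 gene cannot give a p below 0.333.

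**Figure D1:**
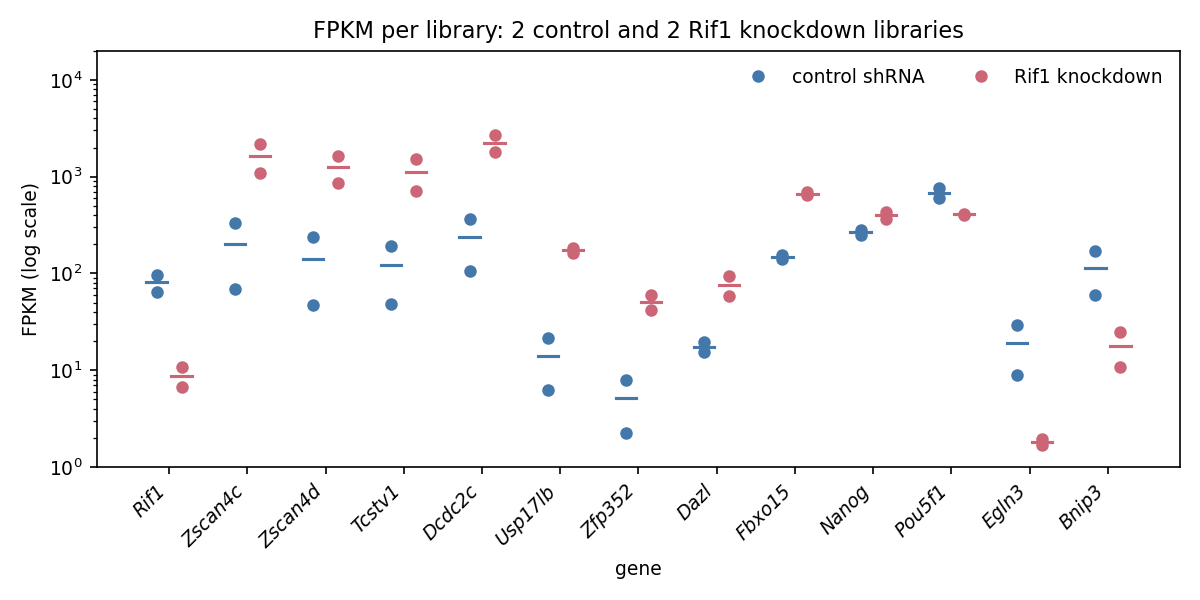
FPKM on a log axis for 13 genes, with 1 point per library (2 control in blue, 2 Rif1 knockdown in red) and a bar at each group's mean. Rif1 fell from 64.1 and 97.3 to 6.73 and 10.8 FPKM, while Zscan4c lay at 68.3 and 334 FPKM in the controls and at 1096 and 2160 FPKM in the knockdown libraries.

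Across the 11786 genes kept, 222 were higher and 180 lower in the knockdown at an adjusted p under 0.05 (limma). The higher genes had a median log2 fold change of 2.18 and a 7.20-fold median ratio of mean FPKM, and the lower genes a median log2 fold change of -1.30. Of the higher genes 221 changed by at least 2-fold, and of the lower genes 156. Both knockdown libraries lay above both controls in 1201 genes and below both in 6489, and the groups did not overlap in 65.2% of genes, where chance alone gives 33.3%. The whole distribution was shifted: the median gene had a log2 fold change of -0.35, a ratio of 0.783, and 80.3% of genes lay below 0. Fold changes are on the scale of log2(FPKM + 1) and understate changes of genes with low FPKM. Median-of-ratios scaling moved that median to -0.01, quantile normalization to -0.07 and scaling to a common sum to -0.15, so the medians of gene lists are given below also relative to the median gene.

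The adjusted p exceeded 0.04 in 141 of the higher and 145 of the lower genes, and the counts moved with the scaling: 17 higher and 4 lower with median-of-ratios factors (81.0% higher, against 55.2% as deposited), of which 8 and 4 are small RNA genes, 11 and 2 with quantile normalization (84.6%) and 128 and 12 with a common sum (91.4%). Leaving out a control library raised the counts, leaving out a knockdown library lowered them, and the 222 and 180 genes kept their direction in each of these settings. They were picked as changed in these same libraries, so their direction could hardly turn.

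**Figure D2:**
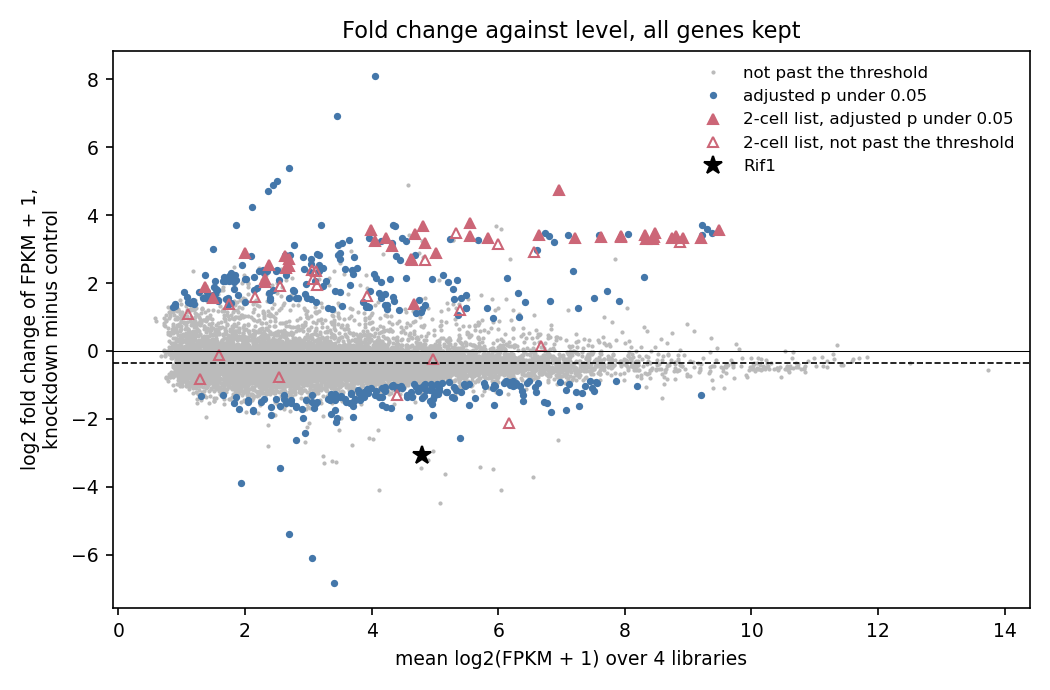
Log2 fold change of FPKM + 1 (knockdown minus control) against the mean log2(FPKM + 1) of the 4 libraries for the 11786 genes kept, with genes past the threshold in blue, members of the 2-cell list as red triangles (filled where past the threshold) and Rif1 as a star. The dashed line marks the median gene at -0.35, and the 2-cell list has its median at 2.89.

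Of the 62 measured members of the 2-cell list, 37 rose, 0 fell and 25 did not pass the test. Adjusted over the list alone, 55 rose and 2 fell, the latter being Zfp750 and Zfp365, named here after their values were seen. The members' log2 fold changes ran from -2.13 to 4.74, with 56 of 62 above 0, and the median lay 3.24 above that of the median gene. Zscan4d rose from 47.3 and 237 FPKM to 860 and 1642 FPKM, a log2 fold change of 3.47 (SE 0.66, adjusted p = 0.0467). Tcstv1 and Tcstv3, a pair of related genes of the 2-cell stage, had log2 fold changes of 3.40 and 3.36. Zscan4f (3.32), Usp17lb (3.77), Usp17la (3.43) and Usp17lc (3.37), the last 3 encoding deubiquitinases, also rose. Zfp352, a zinc finger gene expressed in the 2-cell embryo, went from a mean of 5.13 FPKM to 50.8 FPKM (log2 fold change 3.24, SE 0.45, adjusted p = 0.0334). The highest fold change of the list belonged to BB287469, at 11.6 and 44.4 FPKM in the controls and 457 and 896 FPKM in the knockdown libraries. Gm13043 had the smallest p of the list, with 0.348 and 0.600 FPKM against 8.56 and 11.5 FPKM.

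The 2 control libraries differed in this list, whose mean log2(FPKM + 1) was 3.06 in control 1 and 4.49 in control 2, against 6.10 and 6.31 in the knockdown libraries. In the median member both knockdown libraries exceeded the higher control by at least 1.57 on the log2 scale. The list stood apart from other genes in limma's camera test with a preset correlation of 0.01 (adjusted p = 5.63e-60), and not with the correlation estimated from the data (adjusted p = 0.772 with an estimated correlation). That estimate was 0.551, so 5.63e-60 rests on a correlation far below it. The camera test with an estimated correlation also draws only on the residual degrees of freedom of 4 libraries. Its adjusted p of 0.772 therefore reflects low power as well as the correlation, and does not show that the list is like other genes. Adjustment gave the same 0.772 to lists whose unadjusted camera p ran from 0.0696 in the 2-cell list to 0.571 in the ribosomal list. Most members share sequence with other genes: 50 of 61 members matched to reference transcripts had at least 5% of their 31-base words in transcripts of another gene. The FPKM of a single Zscan4, Usp17l or Tdpoz gene of the list, and of most of its Pramel genes, is therefore uncertain. So is that of BB287469 and Gm13043, with 98.5% and 99.4% of their words shared. After median-of-ratios scaling 58 of the 62 lay above 0 with a median of 3.19, and 1 member, Gm13043, passed the threshold. Both controls of Gm13043 lay under 1 FPKM, so it passed the filter only through the knockdown libraries. Without control 1 the log2 fold changes of Zscan4c and Zscan4f were 2.20 and 2.18.

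Among the 12 characterised genes with the highest fold changes, Tdpoz4, Tdpoz3 and Pramel17 are also members of that list. Spopfm2, Tdpoz4, Tdpoz8 and Tdpoz3, which encode proteins related to the ubiquitin ligase adaptor Spop, had log2 fold changes of 3.70, 3.68, 3.67 and 3.55. Dcdc2c rose from 106 and 366 FPKM to 1797 and 2705 FPKM, and Eif4a3l1 from 30.6 and 110 FPKM to 475 and 841 FPKM. Pramel17 had a log2 fold change of 3.40.

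Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had a median log2 fold change of 0.73, or 1.08 relative to the median gene. Of 62 measured members 2 rose, 0 fell and 60 did not pass the test, and 8 rose and 0 fell when adjusted over the list alone. H4c9 went from 7.11 and 6.88 FPKM to 29.2 and 40.9 FPKM, and H2bu2 from 2.50 and 3.07 FPKM to 7.71 and 13.1 FPKM. Their median level was 4.85 and 2.88 FPKM in the controls and 5.75 and 8.07 FPKM in the knockdown libraries. In the median member both knockdown libraries exceeded the higher control by at least 0.16 on the log2 scale. The camera test gave an adjusted p of 9.21e-21 with the preset correlation, and adjusted p = 0.772 with an estimated correlation. After median-of-ratios scaling these were 1.99e-13 and 0.850, and 0 members passed the threshold.

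Germline and meiosis genes went both ways: of 51 measured members 3 rose, 5 fell and 43 did not pass the test, and 8 rose and 6 fell when adjusted over the list alone. Dazl, an RNA-binding protein of germ cells, rose from 19.6 and 15.3 FPKM to 93.7 and 59.0 FPKM (log2 fold change 2.04, SE 0.27, adjusted p = 0.0271). Mageb4 (2.10) and Slc25a31 (1.43) were the other members that rose, and Syce2 (-1.89), Hsf2bp (-1.63), Tdrd12 (-1.53), Zcwpw1 (-1.46) and Hormad1 (-1.41), which act in meiosis or in the piRNA pathway, fell; Mageb4, Slc25a31 and Zcwpw1 are named after their values were seen. The list's median was 0.44, or 0.80 relative to the median gene, and its mean 0.19, and camera gave an adjusted p of 6.31e-07 with the preset correlation and adjusted p = 0.772 with an estimated correlation. Without control 2 the preset call was lost (adjusted p = 0.267, median 0.15).

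Glycolysis and hypoxia genes had a median log2 fold change of -1.27, or -0.92 relative to the median gene, and 27 of 27 members lay below 0. Of these 6 fell, 0 rose and 21 did not pass the test over all genes, and 23 fell when adjusted over the list alone. Egln3, a prolyl hydroxylase that senses oxygen, fell from 29.5 and 8.81 FPKM to 1.95 and 1.70 FPKM, and Bnip3, a mitophagy receptor induced in low oxygen, from 169 and 60.3 FPKM to 10.8 and 24.6 FPKM. Slc16a3, a lactate exporter, and Tpi1, a glycolytic enzyme, had log2 fold changes of -1.94 and -1.72. The controls differed here too, with median levels of 109 FPKM in control 1 and 62.4 FPKM in control 2, against 30.8 and 29.7 FPKM in the knockdown libraries. Camera gave an adjusted p of 2.07e-07 with the preset correlation, and adjusted p = 0.772 with an estimated correlation. After median-of-ratios scaling these were 8.03e-08 and 0.850. The median was then -0.90 with 27 of 27 members below 0, and 0 members passed the threshold.

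Another 4 lists were lower by camera's preset test, each with adjusted p = 0.772 with an estimated correlation. Cholesterol synthesis genes had a median log2 fold change of -0.63 (adjusted p = 0.00644), with 0 of 24 members past the threshold by limma, 12 lower at an unadjusted p under 0.05 and 10 that fell when adjusted over the list alone. Among its members Srebf2, the transcription factor that drives sterol synthesis genes, had 56.0 and 33.2 FPKM in the controls and 18.9 and 17.2 FPKM in the knockdown libraries. Interferon response genes had a median of -0.60 (adjusted p = 0.0318), with 1 of 20 members, Ifitm2, that fell and 6 that fell when adjusted over the list alone. Replication licensing genes, a list that holds Rif1 itself, had a median of -0.53 (adjusted p = 0.00249): Rif1, Gmnn (90.2 and 80.5 FPKM against 44.0 and 40.1 FPKM) and Gins2 (log2 fold change -0.97) fell, 40 of 43 did not pass the test, and 19 fell when adjusted over the list alone. Ribosomal protein genes had a median of -0.46 (adjusted p = 0.00129), and 1 of 84, Rpl26, fell over all genes and over the list alone. Relative to the median gene the 4 medians were -0.28, -0.24, -0.18 and -0.11, and median-of-ratios scaling ended the calls of the licensing (adjusted p = 0.135) and ribosomal lists (0.46) and those of Gmnn (-0.61), Gins2 (-0.59), Ifitm2 (-0.48) and Rpl26 (-1.10), while Rif1 also left the threshold. Single libraries also ended calls: cholesterol without control 1 (0.334) or knockdown 1 (0.0976), interferon without control 1 (0.089), control 2 (0.104) or knockdown 1 (0.169), licensing without control 2 (0.143), and ribosomal without knockdown 1 (0.981). The interferon call also ended with no filter (0.394), with a mean of at least 5 FPKM (0.175) and with the highest transcript per symbol (0.0518).

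**Figure D3:**
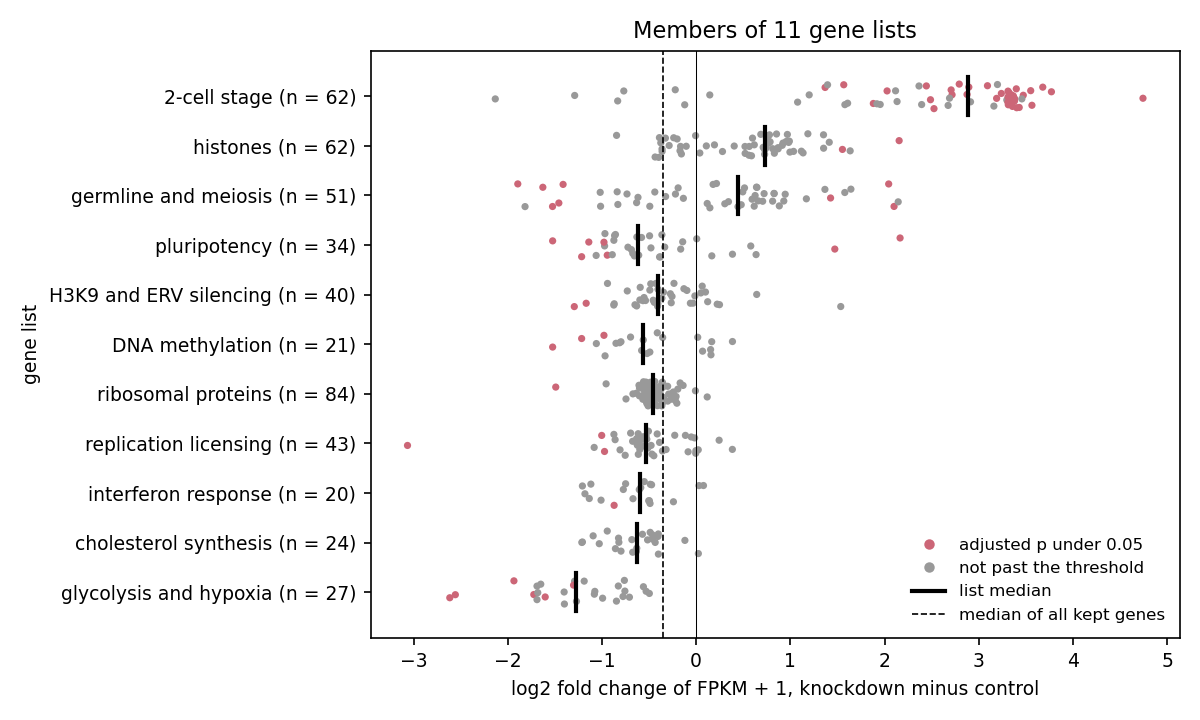
Log2 fold change of FPKM + 1 (knockdown minus control) of each measured member of 11 gene lists, with 1 point per gene (red where the adjusted p is under 0.05), a black bar at the list's median, the number of members in brackets and a dashed line at the median gene (-0.35). The 2-cell list has its median at 2.89 and the glycolysis and hypoxia list at -1.27.

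Pluripotency genes went both ways: of 34 members 2 rose, 5 fell and 27 did not pass the test, and 4 rose (also Nanog and Sall4, the latter named after its value was seen) and 17 fell when adjusted over the list alone (median -0.62, or -0.27 relative to the median gene, camera adjusted p = 0.168). Fbxo15, an F-box gene expressed in embryonic stem cells, rose from 142 and 154 FPKM to 640 and 692 FPKM (log2 fold change 2.16, SE 0.18, adjusted p = 0.00349), and Dppa2, a chromatin factor that activates 2-cell genes, from 50.8 and 87.2 FPKM to 202 and 172 FPKM. Dnmt3l (-1.52), Tet2 (-1.22), Utf1 (-1.14), Tet1 (-0.98) and Esrrb (-0.94) fell. With median-of-ratios scaling these 5 genes and Dppa2 no longer passed, at log2 fold changes of -1.13 for Dnmt3l, -0.85 for Tet2, -0.75 for Utf1, -0.60 for Tet1, -0.55 for Esrrb and 1.86 for Dppa2. Without control 1 camera's preset test called the list lower (adjusted p = 0.00641). The core factors did not pass the threshold: Pou5f1 had 600 and 755 FPKM in the controls and 400 and 414 FPKM in the knockdown libraries (adjusted p = 0.082), Sox2 a log2 fold change of -0.87, Zfp42 of -0.69, Klf4 of -0.63 and Nanog of 0.58. Of 20 genes of formative and primed pluripotency 1, Otx2, fell (log2 fold change -1.97, and -1.21 with adjusted p = 0.218 for the highest of its 4 transcripts in place of their sum), 3 fell when adjusted over the list alone (Otx2, Dnmt3b and Lef1), and the list was not called (median -0.48, or -0.13 relative to the median gene, camera adjusted p = 0.663).

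Factors of heterochromatin and DNA methylation were measured as candidates for the silencing of retroviruses. Of 40 genes for H3K9 methylation and retroviral silencing 2 fell and 0 rose: Ehmt2, an H3K9 methyltransferase, went from 37.6 and 39.8 FPKM to 17.5 and 15.9 FPKM (log2 fold change -1.17), and Mga, a subunit of a repressive Polycomb complex, had a log2 fold change of -1.29. With median-of-ratios scaling Ehmt2 had -0.79 and Mga -0.93, and both left the threshold (limma adjusted p = 0.122 and 0.103). Adjusted over the list alone 1 rose, Zfp809, and 5 fell, among them Cbx5, Chaf1b and L3mbtl2; Zfp809 and L3mbtl2 are named after their values were seen. Setdb1, the H3K9 methyltransferase that silences retroviruses, had 30.8 and 39.4 FPKM in the controls and 36.7 and 35.5 FPKM in the knockdown libraries, and its partner Trim28 a mean of 671 FPKM against 643 FPKM. Their log2 fold changes of 0.05 and -0.03 became 0.43 and 0.36 with median-of-ratios scaling, which turns the sign for Trim28, and neither passed the threshold. Ehmt1 had a log2 fold change of -0.43 that did not pass. The list was not called (median -0.41, or -0.05 relative to the median gene, camera adjusted p = 0.425). Of 21 DNA methylation genes 3 fell (Dnmt3l, Tet1 and Tet2, also members of the pluripotency list), 0 rose and 18 did not pass, with 9 that fell when adjusted over the list alone (median -0.56, or -0.21 relative to the median gene, camera adjusted p = 0.13, and 0.0459 without control 1). Dnmt1 (-0.52), Dnmt3a (0.07), Dnmt3b (-0.81) and Uhrf1 (-0.70) did not pass the threshold.

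Of 23 immediate early and stress genes 3 rose and 1 fell (median -0.36, or -0.01 relative to the median gene, adjusted over the list alone 3 and 4, camera adjusted p = 0.227). Hspa1a rose from 5.95 and 8.03 FPKM to 51.3 and 56.3 FPKM (log2 fold change 2.79, SE 0.23, adjusted p = 0.00347) and Hspa1b, a near-identical copy, by 2.68, while Jun rose by 1.57 and Ier3 had a log2 fold change of -1.65. Egr1, Trib3 and Chac1, named after their values were seen, were the other members lower over the list alone. Hspa1a, Hspa1b, Fbxo15 and Dazl also passed the threshold after median-of-ratios scaling. Of 320 zinc finger protein genes Zfp352, Zfp560 (2.83) and Zfp51 (1.68) rose and Zfp459 (-1.85) and Zfp532 (-1.34) fell, the last named after its value was seen (adjusted over the list alone 3 and 1, median -0.30, or 0.05 relative to the median gene, camera adjusted p = 0.425).

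Markers of other cell types were few among the genes kept. Of 10 endoderm markers Foxa1 rose from 1.08 and 1.06 FPKM to 4.74 and 3.87 FPKM and 0 fell, and adjusted over the list alone 1 rose and 2 fell (Lamc1 and Apoe). Of 4 mesoderm markers Snai1 rose (log2 fold change 1.55) and Bmp4 fell (-1.49), over the list alone as well. By limma 0 of 9 ectoderm, 12 trophectoderm, 9 fibroblast and 3 Polycomb-bound developmental genes passed the threshold over all genes or over the list alone, and at an unadjusted p under 0.05 there were 1, 2, 1 and 0. Camera called 0 of these 6 lists (smallest adjusted p = 0.063). Without knockdown 2 the ectoderm list was called (adjusted p = 0.00769), with its median going from -0.04 to 0.77, as it was with the highest transcript per symbol (0.0488) and with no filter (0.00361). With no filter camera also called the fibroblast (0.0378), Polycomb-bound (0.000107), pluripotency (0.00936), H3K9 silencing (0.016), DNA methylation (0.0242) and repair lists (0.00122). Of 25 imprinted genes 1, Magel2, rose from 0.197 and 0.559 FPKM to 2.34 and 3.26 FPKM and 0 fell, and when adjusted over the list alone Ndn rose too and Grb10, named after its value was seen, Phlda2 and Zdbf2 fell (camera adjusted p = 0.218). By limma 0 of 31 p53 targets passed over all genes, with 2 higher and 7 lower at an unadjusted p under 0.05, and adjusted over the list alone Plk2 rose and Bbc3, Bax and Ei24 fell (camera adjusted p = 0.903). Cdkn1a, the cell cycle inhibitor induced by p53, had 19.3 and 9.30 FPKM in the controls and 13.1 and 4.74 FPKM in the knockdown libraries. By limma 0 of 34 repair and telomere genes passed over all genes, with 15 lower at an unadjusted p under 0.05 and 9 that fell when adjusted over the list alone (median -0.55, or -0.20 relative to the median gene, camera adjusted p = 0.0828). Of the 23 lists tested 8 were called with the preset correlation and 0 with an estimated correlation, where 0 were at an unadjusted p under 0.05. The test with an estimated correlation had little power on 4 libraries, so its 0 calls decide little. With fry, which tests whether a list's genes move 1 way on balance, 0 lists were called (smallest adjusted p = 0.227, 2 at an unadjusted p under 0.05), and 9 were called for change in either direction. The 9 did not include the 2-cell (fry adjusted p = 0.0855), histone (0.0855), germline (0.0714) or glycolysis lists (0.105).

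The genes with the lowest fold changes after Rif1, Egln3 and Bnip3 came from several functions. Aire, the transcriptional regulator known from thymic tolerance, was 7.17-fold lower in the knockdown (log2 fold change -2.41, SE 0.28, adjusted p = 0.0209). Sox15, a transcription factor of the Sox family, fell from 19.4 and 21.8 FPKM to 3.85 and 5.28 FPKM, and Scd1, a fatty acid desaturase, from 36.0 and 16.6 FPKM to 7.23 and 4.37 FPKM. Slc17a9, a vesicular nucleotide transporter, had a log2 fold change of -1.89. Hypk, a partner of an N-terminal acetyltransferase, fell from 197 and 229 FPKM to 53.8 and 67.4 FPKM (log2 fold change -1.80, SE 0.20, adjusted p = 0.0163). Actb had a log2 fold change of 0.09 that became 0.48 with median-of-ratios scaling, and Gapdh one of -0.76 that became -0.36; neither passed the threshold.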

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

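The tests without small RNA genes and with the replicate block plus median-of-ratios scaling were chosen after the result was seen. Each of the 222 higher and 180 lower genes kept its direction in each setting that tested it, while the number past the threshold changed, and the cause was not tested except where stated.

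Genes higher and lower numbered 36 and 14 with a pseudocount of 0.1, 166 and 91 with 5, 11 and 5 at a mean of 5 FPKM or more, 17 and 4 with median-of-ratios scaling, 11 and 2 with quantile normalization, 128 and 12 at a common sum, 21 and 7 without the trend and 29 and 8 with the highest transcript per symbol. Without a filter limma called 0 and 0 (1115 and 2818 at an unadjusted p under 0.05, smallest adjusted p = 0.163). The replicate block gave 633 and 1665, leaving out small RNA genes 444 and 811, and the block with median-of-ratios scaling 849 and 314. Nothing in the labels pairs libraries of the same number, whose deviations correlated at 0.173 across genes. Leaving out each library gave 5 to 602 higher and 7 to 1869 lower genes. There the lone library is assumed to vary like the other group.

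Rif1 stayed lower throughout and left the threshold with median-of-ratios scaling (-2.69, adjusted p = 0.0778), quantile normalization (-2.78, adjusted p = 0.095) and no filter (-3.07, adjusted p = 0.203). Leaving out each library gave -3.37 to -2.76, and the call was lost without either knockdown library. Of 60 named genes past the threshold, 55 lost it with median-of-ratios scaling, 58 with quantile normalization, 32 at a common sum, 60 without a filter and 60 without either knockdown library, while 0 lost it with the block or without a control library.

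The 8 lists called became 14 without a filter, 0 with an estimated correlation and 5 to 9 with a library left out. The 2-cell median was 2.89 with an estimated correlation (adjusted p = 0.772), and 2.05 to 3.76 with a library left out.

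Signs turned in genes that did not pass the threshold. Vim (-0.19) had 0.20 with median-of-ratios scaling, alone or with the block, 0.09 with quantile normalization and 0.05 at a common sum. Mesp2 (-0.07) had 0.14, 0.07 and 0.08, and 0.14 with the block. Trim28 (-0.03) had 0.36 with median-of-ratios scaling, alone or with the block, and 0.21 at a common sum. With a library left out Vim ran from -0.47 to 0.09, Nkx2-9 from -0.55 to 0.01, Setdb1 from -0.12 to 0.22, Trim28 from -0.34 to 0.27, Dnmt3a from -0.24 to 0.38 and Actb from -0.24 to 0.41. In a simulation with 2 libraries per group, changes of 2-fold were recovered in 0% of genes. It modelled neither sequencing depth nor the shift of the median gene. The test on the real data called some lower genes below 2-fold, such as Gins2 (-0.97), so the 0% does not give its power here.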

Other observations

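The tests of families, shared sequence, permuted libraries and single reads, the use of median-of-ratios scaling to weigh explanations, and the block with that scaling were chosen after the result was seen, while median-of-ratios scaling itself was planned.

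Several gene families were over-represented among the 222 higher genes by a one-sided Fisher's exact test over 718 tests. These were Pramel genes, with 11 of 20 higher (adjusted p = 8.59e-12), Tdpoz genes with 7 of 7 (2.75e-10), olfactory receptor genes with 7 of 15 (1.04e-06), Fthl17 genes with 5 of 6 (2.4e-06) and Usp genes with 6 of 49 (0.0426). Of these higher genes the 2-cell list holds 4 Pramel, 4 Tdpoz, 1 olfactory receptor, 0 Fthl17 and 5 Usp genes. Above 0 after median-of-ratios scaling were 19, 7, 14 and 6 members of the first 4 families, but of the higher genes of all 5 families 1, Olfr881, still passed the threshold there. Usp genes were mixed: of 49, 6 were called higher, 10 lay above 0 as deposited and 26 lay above 0 after scaling. Fthl17c, an X-linked ferritin-like gene, rose from 0.435 and 0.720 FPKM to 4.01 and 4.95 FPKM. Genes with both controls under 1 FPKM passed the filter only through the knockdown libraries. Among the higher genes of the families this held for Fthl17b, Fthl17c, Fthl17d, Fthl17e, Olfr20, Olfr450, Olfr787, Olfr814, Olfr881, Tdpoz1 and Usp9y. The shares and p-values of the olfactory receptor, Fthl17, Tdpoz and Usp families therefore rest partly on that filter and can be too strong.

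The 2-cell genes had a median log2 fold change of 2.89, and 3 technical explanations were weighed. Library scaling is argued against, since the median was 3.19 after median-of-ratios scaling, although 1 member passed the threshold there, against 37 as deposited. The median gene lay at -0.35, so the shift of the libraries ran opposite to the list. Rescaling could therefore only raise the list's median, and its direction was known beforehand. Reads shared between near-identical copies are argued against as the whole cause: the 11 members with under 5% of their words in another gene had a median of 1.58, 1.93 above all genes, with a median absolute deviation of 0.91 and a range of -0.83 to 2.68; 7 of them lay above 0, 3 were called higher, and Zfp750 and Zfp365 are among them. The 50 members with shared sequence had a median of 3.19 with 33 called, so shared reads stay open as part of the size of the change. Spread between cultures cannot be told apart from the knockdown, since the labels do not say which libraries share a culture; an exact permutation over 3 splits cannot give a p under 0.333 and so decides nothing, with a list mean difference of 2.42 in the real split and 0.82 in the highest other, and the knockdown itself stays open, with no further test here.

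The 180 genes lower as deposited had a median of -1.30, and -0.92 after median-of-ratios scaling, where 4 of them stayed past the threshold: Mir20a, Mir7005, Snord111 and Snord88a, all small RNA genes. With the replicate block as well, 127 of them passed, although nothing in the labels pairs the libraries. Rif1, the target named in advance, had -2.69 after scaling (adjusted p = 0.0778). The genes were picked on the unscaled values, so their median after scaling decides nothing. For these genes as a set a difference in library scaling and lower expression cannot be told apart, and the cause of the lost calls was not tested. The glycolysis and hypoxia list, written in advance, had a median of -0.90 after scaling with 27 of 27 members below 0. For that list this argues against scaling as the whole cause, although 0 members passed the threshold there. The licensing and ribosomal lists lost their preset camera calls with the same scaling.

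Of the genes past the threshold 14 higher and 10 lower were small RNA genes. For the 12 listed at 0 in each library of 1 group, the depth-scaled values of the other group stood in ratios of whole numbers up to 4, within a relative tolerance of 0.05, in 100% of genes, against 40.4% of other genes. Single reads on very short transcripts are therefore a likely source of these 12 calls, and no biological explanation was tested.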
